A study of Rattus norvegicus with 10 samples.

How the data were processed

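Total RNA of 10 rat liver samples was depleted of ribosomal RNA, made into paired-end libraries with a mean insert of 300 bp and sequenced on an Illumina instrument, per the labels' protocols. RNA integrity numbers were above 7.0 and about 5 µg of RNA entered each library, per the labels. Samples were assigned to the sleeve gastrectomy or the sham group from their labels, 5 in each. The labels describe rats assigned at random to the groups and do not say that each sample came from its own rat, so p-values measure the spread between these samples. Rats entered the groups at a fasting glucose above 16.7 mmol/L 3 days after streptozotocin, which was given after 16 h of fasting. The hour at which livers were taken is not given in the sources used here.

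The submitters' processing notes name cutadapt 1.9, FastQC 0.10.1, HISAT2 2.0.4 and StringTie 1.3.4, and the genome build Rnor_6.0. The authors deposited 1 table of 51430 isoforms, with FPKM and estimated counts of each isoform in each library. The deposited FPKM values are in fragments per kilobase of transcript scaled to library size, per the file headers. The estimated counts that the authors deposited are whole numbers, proportional within a library to FPKM times length, so isoforms share reads by estimate and p-values from count models rest on estimates. The table marks 28040 isoforms by a reference identifier and 23390 as assembled, and 469 isoforms stood at 0 in every library. Coordinates are those of the table. Symbols and biotypes came from a RefSeq table of another assembly, GRCr8, used for names only, and 15769 of the gene names matched it. Mitochondrially encoded messenger RNAs were not analysed here.

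Gene values were sums over the isoforms that match, are contained in, share a junction with or overlap a reference gene on the same strand, which gave 20681 genes. This definition was chosen after the columns of the table were seen and before any comparison of groups. Genes sharing reads with close copies, such as the Mup, Cyp4a and immunoglobulin families, are uncertain because the assembler could split reads between them. Genes entered the test at a mean of at least 1 FPKM, which left 11021. Transcripts entered when above 0 in at least 5 libraries with a mean of at least 0.1 FPKM. Long non-coding transcripts were annotated transcripts of at least 200 nt that the symbol table gives as long non-coding or antisense RNA, that carry a name from the list of known long non-coding RNAs, or that the table describes as non-coding.

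The planned test was limma on log2(FPKM + 0.5) for genes and log2(FPKM + 0.1) for transcripts, with edgeR for genes should counts be present. Because the table holds estimated counts, edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on rounded counts became the main test for genes and also for transcripts, a departure from the plan for transcripts. Limma 3.58.1 on the FPKM values is given beside it. Counts were scaled by the trimmed mean of M values, p-values were two-sided and adjusted by Benjamini-Hochberg, and 0.05 was the threshold. Standard errors were derived from the F statistic. Limma on FPKM gave a median log2 fold change of 0.08 over all genes, against -0.008 in edgeR. DESeq2 1.42.0 was added after the data were seen.

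Gene lists were fixed before the data were examined, 34 in all, and 25 had at least 5 tested members. They covered gluconeogenesis, glycolysis and glycogen, fatty acid synthesis, cholesterol synthesis, bile acids, fatty acid oxidation, lipoproteins, insulin signalling, the growth hormone axis, the unfolded protein response, NRF2, acute phase, interferon, inflammation, extracellular matrix, oxidative phosphorylation, xenobiotic metabolism, clock, urea cycle, cell cycle, stress genes, known long non-coding RNAs and markers of 11 cell types, with mitochondrially encoded messenger RNAs as the remaining list. The result of 1 cell type list and those of some genes are not reported here. Lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Named genes were fixed names, 14 of them reported here, the 5 smallest p-values in each direction where fewer than 10 passed, and up to 4 members with the smallest p of each list with a result to describe. Circadian clock, cholesterol synthesis and B and plasma cell lists were added to those described after their values were seen. Named transcripts were those that passed, or the 3 smallest p-values in a direction. Mean list scores are centred log2 CPM.

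Group separation was tested by exact permutation over all splits of the libraries into 5 and 5, and pairs of long non-coding RNA and nearest gene by 1000 random pairings, one-sided. Only tested protein-coding genes were searched. Genes overlapping the transcript were passed over for the next gene, where the plan was to leave out pairs overlapping in exons. Library measures were compared by exact permutation tests over a family of 11 measures, reduced after the p-values were seen. Libraries correlated at a Spearman rho of 0.936 to 0.972, and no 2 libraries agreed within sampling noise. The scripts' tests were tested on simulated data with known changes, where a list of 25 genes raised 1.5-fold was called and 0 of 24 random lists were. Simulated genes were drawn independently, so this says nothing about false calls for lists whose members move together. In these libraries the estimated correlation was 0.72 for the interferon list, and other splits called a median of 8 of the 25 lists. Folds against a group at 0 use a floor of 3 counts over the group. Intervals and floors on counts cover counting error only. Alternatives covered pseudocounts, filters, scalings, test settings, a block for the replicate number and leaving out each library. Alternatives added after the data were seen were DESeq2, other gene definitions, the clock score or the ribosomal share as a covariate, leaving out SG 2 and SHAM 5 together, an unfiltered list test, an estimated correlation for lists called only under an alternative, left-out libraries for those called without a filter or with the clock score, and pairs of assembled intergenic loci with genes. The pathways named in the deposited table, the ribosomal protein and immunoglobulin groups, the test of summed loci and the share of intergenic reads without ribosomal loci were also chosen after the data were seen.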

Results

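Liver RNA was profiled in 10 samples from diabetic Wistar rats, 5 after sleeve gastrectomy (SG) and 5 after a sham operation (SHAM). Sleeve gastrectomy removes most of the stomach and leaves a narrow tube. The rats had been made diabetic with a diet that gave 60% of its calories as fat for 4 weeks, followed by 35 mg/kg streptozotocin, a toxin of pancreatic beta cells. The labels place the SG livers at 3 months after surgery and give no time for the SHAM livers, so any difference in time cannot be told apart from the operation. The series was made to profile long non-coding RNAs after this operation. Total estimated counts per library ranged from 77617460 to 92110190 in SG and from 65824088 to 85520959 in SHAM. With 5 libraries in each group, the 95% confidence interval of a gene had a median half-width of 0.37 on the log2 scale. The interval lay within a 2-fold change either way for 9360 of 11021 tested genes (84.9%).

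Which liver genes differed between SG and SHAM rats was asked first. The lowest p-values among genes with higher values in SG belonged to LOC103690996 (log2 fold change 1.52 ± 0.28 SE), the ribosomal protein gene Rpl5 (0.54 ± 0.11) and 5330417C22Rik (1.63 ± 0.35), and also to AABR07045485 (0.61 ± 0.12) and AABR07064810 (1.61 ± 0.34). Rpl5 had 47.6 ± 11.4 FPKM in SG and 27.5 ± 6.60 FPKM in SHAM (SD, n = 5). On the lower side stood Taf9, which encodes a subunit of the general transcription factor TFIID (-1.56 ± 0.33), Dennd1b, an activator of the small GTPase Rab35 (-0.41 ± 0.08), and Inafm1 (-1.02 ± 0.24), with AABR07063425 (-2.94 ± 0.71) and the ubiquitin-like conjugating enzyme Ube2l6 (-0.76 ± 0.19). AABR07063425 had 1116.73 to 3460.5 FPKM in SHAM 2 to SHAM 4, but 315.44 in SHAM 1 and 212.99 in SHAM 5, against 216.58 to 311.53 in SG. For Dennd1b the mean FPKM differed less than the counts, at 4.94 in SG and 5.36 in SHAM. None of these 10 genes passed the test in edgeR (adjusted p = 0.993 for each).

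Across all 11021 genes, 0 passed at an adjusted p of 0.05 in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 509 genes, 307 higher and 202 lower in SG, where 551 would be expected with no difference. Limma on log2(FPKM + 0.5) also called 0 genes, with 718 at an unadjusted p under 0.05, of which 661 were higher and 57 lower. FPKM were not scaled further there, and the median log2 fold change over all genes was 0.08. On TPM, where that median was -0.015, limma gave 222 higher and 123 lower. DESeq2, added after the data were seen, called 16 genes (11 higher, 5 lower), with 620 at an unadjusted p under 0.05. They included 9 of the 10 genes above, and the other members were Ighg1, Mageh1, Ube3d, AABR07034739, AABR07044404, AABR07051708 and LOC108348082. LOC108348082 was above 0 only in SHAM 3 and SHAM 4. In simulated data of this size, edgeR recovered 53% of 2-fold and 94% of 4-fold changes. Without SG 5 edgeR called 1 gene, AABR07072266, which stood at 0 FPKM in SG 1 to SG 4, 3.33 in SG 5 and 2.36 to 4.76 in SHAM. Without SHAM 1 it called 1 other gene, Mir30a (2.55 to 3.25 FPKM in SG, 3.56 in SHAM 1 and at most 0.02 in the other SHAM libraries); these genes were singled out after their values were seen.

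Genes of glucose and insulin metabolism fixed before the data were examined stayed near equal levels or varied widely within groups. Pck1, the rate-limiting enzyme of gluconeogenesis, had 886 ± 236 FPKM in SG and 904 ± 405 in SHAM (SD, n = 5), and G6pc, the catalytic subunit of glucose-6-phosphatase, 34.5 ± 19.1 and 28.3 ± 12.1. The insulin receptor gene Insr ranged from 27.5 to 31.5 FPKM in SG and from 23.6 to 33.9 in SHAM. Its log2 fold change was -0.02 with a 95% interval from -0.24 to 0.19, which excludes a 1.5-fold change. The insulin receptor substrate gene Irs2 had a log2 fold change of 0.48 ± 0.28 (SE), which was 0.26 without SG 2, and Igfbp1 one of -0.27 ± 0.35, which ranged from -0.41 without SG 2 to -0.06 without SG 3. The signs for Pck1 and Insr were positive in limma on log2(FPKM + 0.5), at 0.03 and 0.07. With 1 library left out the sign turned for Pck1 without SG 3 (0.03), SG 5 (0.05) or SHAM 2 (0.19), for G6pc without SG 4 (-0.08) or SHAM 2 (-0.03), and for Insr without SHAM 2 (0.03). None of these genes passed (edgeR, adjusted p = 0.993, or 0.996 for Pck1).

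Bile acid and lipid genes showed the widest gaps among the fixed names, and none passed in edgeR (adjusted p = 0.993, or 0.996 for Cpt1a). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 38.6 ± 40.1 FPKM in SG and 102 ± 35.3 in SHAM (SD, n = 5). Its log2 fold change was -1.45 ± 0.68 (SE, edgeR unadjusted p = 0.0578), with SG 1 at 108 FPKM and the other SG libraries at 2.55 to 28.6, and was -2.24 without SG 1. Cyp8b1, which sets the share of cholic acid, stood at -0.48 ± 0.43, which was -0.06 without SHAM 4 and -0.73 without SG 2. Nr0b2, a repressor of bile acid synthesis, stood at -0.22 ± 0.65, which was 0.07 without SG 2 and 0.13 without SHAM 5. Srebf1, a transcription factor of fatty acid synthesis, had a log2 fold change of -0.71 ± 0.38 (-0.34 without SHAM 4) and the fatty acid synthase gene Fasn 0.36 ± 0.66, which was -0.13 without SG 1. Scd, a fatty acid desaturase, had 155 FPKM in SG 2 and 0.86 to 3.73 in the other SG libraries, and its log2 fold change of 1.77 turned to -2.29 without SG 2. Fgf21, a hormone of the fasted liver, reached 37.8 FPKM in SHAM 4 against 0.51 to 4.38 in the other SHAM libraries, and its log2 fold change of -1.41 turned to 0.81 without SHAM 4 and stood at 0.02 in limma on log2(FPKM + 0.5). Cpt1a, which brings fatty acids to oxidation in mitochondria, stood at -0.06 ± 0.28 and Ppargc1a at -0.10 ± 0.25 (0.05 without SHAM 2). The value of Cpt1a was 0.00 without SG 3, 0.08 without SG 5, 0.05 without SHAM 1 and 0.07 without SHAM 2.

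**Figure D1:**
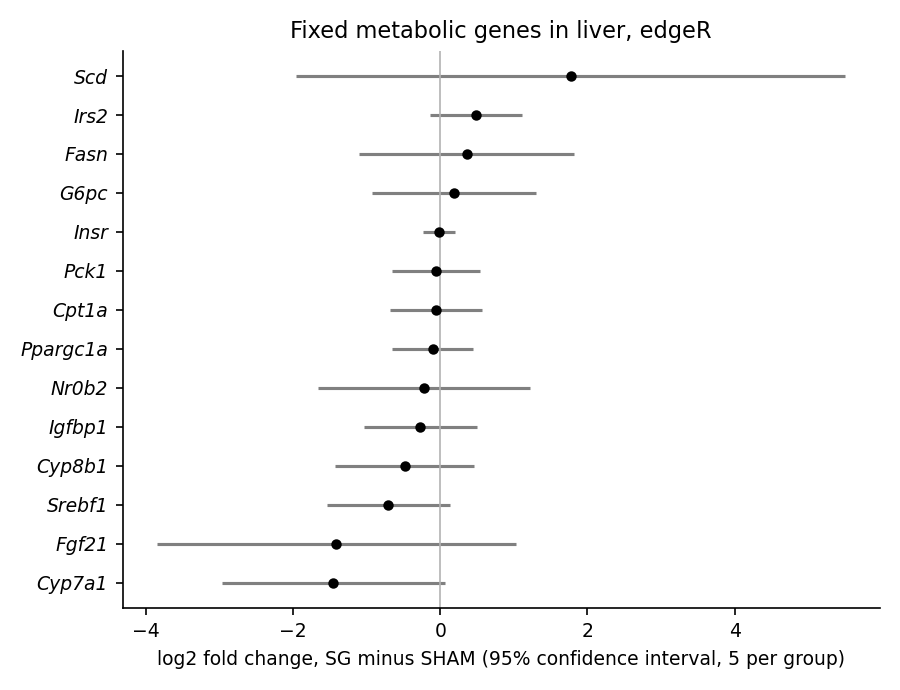
Log2 fold changes (SG minus SHAM, edgeR, horizontal axis) of 14 metabolic genes fixed before the data were examined, with 95% confidence intervals from 5 libraries per group. Every interval spans 0, from the narrow one of Insr (-0.24 to 0.19) to the wide one of Scd (-1.96 to 5.50).

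Interferon response genes, which cells switch on against viruses, were lower in SG as a list. All 26 tested members had a negative log2 fold change, with a median of -0.88, and 10 had an unadjusted p under 0.05. Usp18, a brake on interferon signalling, stood at -2.54 ± 0.92 (SE), the transcription factor genes Irf7 at -2.54 ± 0.94 and Irf9 at -1.02 ± 0.35, and Ifi27 at -0.68 ± 0.23. Much of the difference lay in SHAM 5: Usp18 reached 49.2 FPKM there and 1.70 to 6.23 in the other SHAM libraries, and the mean list score was 2.40 in SHAM 5 and -0.77 to 0.17 in the other 9. Without SHAM 5 Usp18 stood at -0.67, Irf7 at -0.70, Irf9 at -0.75 and Ifi27 at -0.49. SHAM 1 was also above every SG library for each of these genes (285 FPKM for Ifi27). So was SHAM 2 for Usp18 and Ifi27, and SHAM 4 for Irf7 and Ifi27, while SHAM 3 was for none of them. These genes were named for the smallest p-values of the list. For Irf9 the mean FPKM differed less than the counts, at 3.115 in SG and 4.361 in SHAM. Over the whole list the scores of SHAM 2 (-0.52), SHAM 3 (-0.46) and SHAM 4 (-0.12) lay within the SG range (-0.77 to -0.06). SHAM 1 stood at 0.17. The list was the 1 of 25 that passed camera with a preset correlation of 0.01 (adjusted p = 1.49e-08). With an estimated correlation its p was 0.15 and with fry's test for 1 direction its p was 0.274, and neither called any list. Without SHAM 5 the median was -0.06 and the list no longer passed (camera adjusted p = 0.249; 8.46e-15 to 0.85 over all alternatives). The number of lists passing camera was 3 without SG 1, 10 without SG 3, 6 without SG 5, 2 without SHAM 3 and 5 without each of SG 2, SG 4, SHAM 1, SHAM 2, SHAM 4 and SHAM 5. Other splits of the same libraries into 5 and 5 called a median of 8 of the 25 lists. No single member passed over all genes or adjusted over the list alone (0 genes, edgeR).

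**Figure D2:**
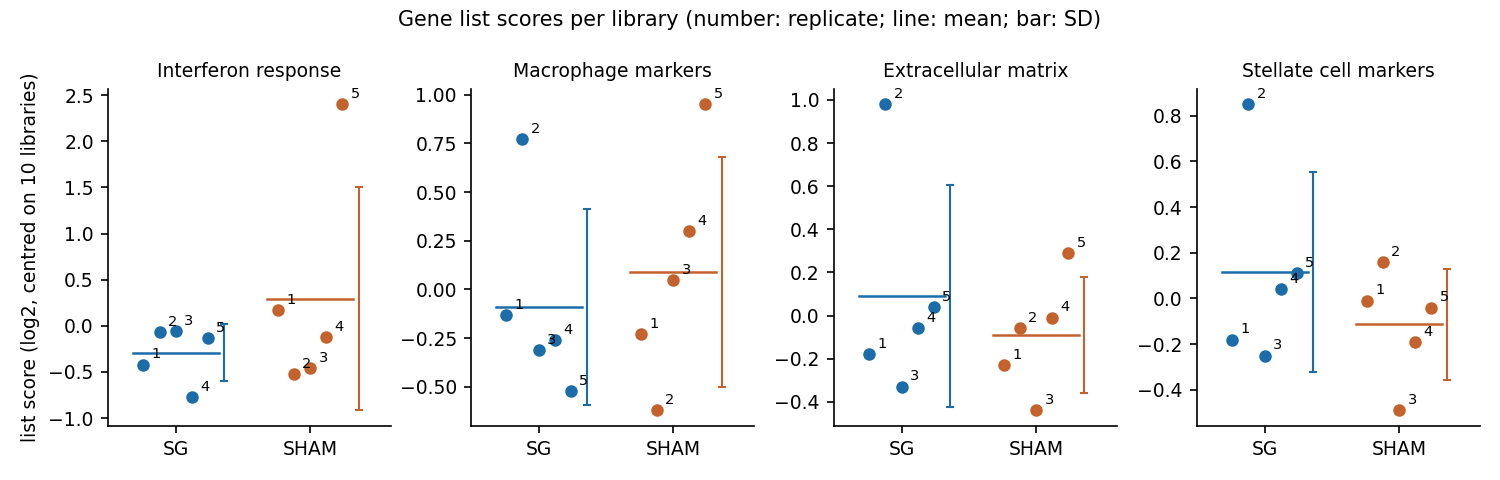
Mean list scores per library (vertical axis, centred log2 CPM) for 4 gene lists, with each replicate numbered, lines at group means and bars for the SD of 5 libraries. SHAM 5 stands apart for interferon genes at 2.40, and SG 2 for extracellular matrix genes at 0.98.

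Metabolic lists other than interferon did not pass camera (adjusted p from 0.0595 to 0.987), and no member of them passed adjusted over the list alone. Genes of the urea cycle and amino acid breakdown had a median log2 fold change of -0.16 (-0.08 without SHAM 2), with 20 of 23 members negative. Among them the serine dehydratase gene Sds had -1.86 ± 0.88 (SE), with 92.7 FPKM in SHAM 2 and 3.41 to 11.3 in the other SHAM libraries, and -0.18 without SHAM 2, while the ornithine transcarbamylase gene Otc had 0.35 ± 0.16. The urea cycle list had a camera p of 0.00476 and an adjusted p of 0.0595. Fatty acid oxidation and PPAR alpha targets had a median of 0.05, which ranged from -0.06 without SG 1 to 0.19 without SHAM 4, with the fatty acid binding protein gene Fabp1 at 0.74 ± 0.21 and 270 ± 44.2 FPKM in SG against 151 ± 36.5 in SHAM (SD, n = 5). Cyp4a8, a fatty acid hydroxylase, stood at 2.31 ± 0.87 (3.52 without SHAM 2). Nuclear genes of oxidative phosphorylation had a median of 0.04 (-0.01 without SG 4 or SHAM 5), with Cox6c (0.39 ± 0.10), Ndufa4 (0.28 ± 0.09) and Ndufb3 (0.31 ± 0.11) positive and Uqcrfs1 (-0.39 ± 0.16) negative. By fry's test for change in either direction this list had an adjusted p of 0.00844, the 1 list of 25 under 0.05 there. The growth hormone axis had a median of 0.20 (as low as 0.06, without SHAM 2), with the major urinary protein gene Mup4 at 1.46 ± 0.53 (0.87 without SG 4) and Igf1 at 0.23 ± 0.26 (0.11 without SG 2, SHAM 3 or SHAM 5, and up to 0.45 without another library). The unfolded protein response had a median of -0.12 (-0.07 without SHAM 3), with Calr at -0.26 ± 0.16 and Atf4 at -0.22 ± 0.15 (-0.14 without SHAM 3, -0.13 without SHAM 4). The urea cycle list passed without SG 3, SG 4, SG 5, SHAM 4 or SHAM 5 (camera adjusted p from 0.00505 to 0.0301) and the fatty acid oxidation list without SG 2, SG 3 or SHAM 4 (0.000264 to 0.0282). Likewise the oxidative phosphorylation list passed without SG 2, SG 3 or SHAM 3 (0.00943 to 0.0168), the growth hormone axis without SG 3 or SHAM 4 (0.0446 and 0.0464) and the unfolded protein response without SG 4, SHAM 2 or SHAM 5 (0.0182 to 0.0335). These calls did not hold with an estimated correlation: in the same fits the p-values were 0.161 to 0.323 for the urea cycle, 0.103 to 0.347 for fatty acid oxidation, 0.295 to 0.342 for oxidative phosphorylation, 0.0846 to 0.113 for the growth hormone axis and 0.208 to 0.252 for the unfolded protein response.

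The remaining pathway lists also did not pass. Among them were gluconeogenesis (median -0.07, 13 members), fatty acid synthesis (-0.00, 16 members), cholesterol synthesis (0.10, 24 members), bile acid synthesis and transport (-0.10, 21 members) and insulin and IGF signalling (-0.03, 21 members). NRF2 targets stood at -0.11, acute phase genes at 0.18, inflammation at 0.00, xenobiotic metabolism at -0.13, circadian clock genes at -0.13 and immediate early and heat shock genes at 0.07, which ranged from -0.07 without SG 5 to 0.29 without SG 3. For glycolysis and glycogen (-0.07) and lipoproteins (-0.01) the camera direction was up, opposite to the median, and for cell cycle genes (0.04, only 5 of 26 members present being tested) it was down. The mean was positive for fatty acid synthesis (0.08) and bile acids (0.03), opposite to their camera direction, and negative for cell cycle genes (-0.09). Acute phase genes passed without SG 3, SG 5 or SHAM 1 (camera adjusted p from 0.0224 to 0.0466), cholesterol synthesis without SG 2, SG 5 or SHAM 1 (0.032 to 0.048), NRF2 targets without SHAM 2 (0.0393, median -0.22) and immediate early genes without SG 3 (0.0301). The NRF2 median ranged from -0.22 to -0.0 with 1 library left out. None of these calls held with an estimated correlation, at p-values of 0.3 to 0.371 for acute phase genes, 0.524 to 0.554 for cholesterol synthesis, 0.119 for NRF2 targets and 0.155 for immediate early genes. With the clock score as a covariate, a setting added after the data were seen, the cholesterol synthesis list passed (camera adjusted p = 2.51e-07, 3.09e-17 to 0.115 with 1 library left out) at a median of 0.35. With an estimated correlation its p there was 0.191, and it did not pass without SHAM 5. Other directions that turned with 1 library left out are given with the alternatives.

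Some markers of other liver cell types stood apart in single libraries. In SG 2 the macrophage lysozyme gene Lyz2 stood at 81.6 FPKM against 14.6 to 20.1 in the other SG libraries, the fibrillar collagen gene Col1a1 at 5.25 against 0.37 to 0.93, and the smooth muscle actin gene Acta2 at 4.67 against 1.29 to 1.83. The macrophage and Kupffer cell score was 0.77 in SG 2 and 0.95 in SHAM 5, and between -0.62 and 0.30 in the other 8 libraries. Extracellular matrix genes had a median log2 fold change of 0.13, which was -0.10 without SG 2, and stellate cell and fibroblast markers one of 0.26, which was 0.03 without SG 2. Macrophage markers had a median of -0.34, which was 0.03 without SHAM 5. Hepatocyte markers stood at -0.08 (-0.13 without SG 4, -0.04 without SG 3 or SHAM 1) and endothelial markers at 0.07 (0.24 without SHAM 5 and as low as 0.0 without another library), and none of these lists passed camera (adjusted p from 0.0618 to 0.266). With 1 library left out, extracellular matrix genes passed without SG 1, SG 3, SG 4, SG 5 or SHAM 5 (camera adjusted p from 0.00175 to 0.0487), and stellate cell markers without any 1 library except SG 2, SHAM 3 and SHAM 4 (0.00136 to 0.0487). Macrophage markers passed without SG 2, SHAM 1 or SHAM 2 (1.21e-05 to 0.0466) and endothelial markers without SG 3, SHAM 4 or SHAM 5 (0.0436 to 0.0484). None of these held with an estimated correlation, at p-values of 0.25 to 0.428 for extracellular matrix, 0.156 to 0.324 for stellate cell, 0.159 to 0.419 for macrophage and 0.343 to 0.369 for endothelial lists. Lists with too few tested members for a test had medians of -0.31 (T and NK cells, Cd4 alone), 0.47 (B and plasma cells), -1.04 (red blood cells, 4 members), -0.67 (pancreatic acinar cells, Cela1 alone) and 0.07 (adipocytes). Neutrophil markers had 0 tested members. Without a filter on low values, red blood cell markers (6 members, median -0.98, camera adjusted p = 0.00139) and B and plasma cell markers (10 members, median 0.63, adjusted p = 0.0446) passed. With an estimated correlation their p-values were 0.0603 and 0.24. With 1 library left out they passed in 6 and 1 of 10 fits, red blood cell markers not without SG 2, SHAM 3, SHAM 4 or SHAM 5 and B and plasma cell markers only without SHAM 5. Among the cell type lists reported here, adjusted over the list alone, 1 plasma cell gene passed, Jchain (1.12 ± 0.40 SE, 33.3 ± 17.3 FPKM in SG and 13.3 ± 6.98 in SHAM), in a list of 2 tested genes. Without both SG 2 and SHAM 5, a setting added after the data were seen, edgeR called 1 gene (Klhdc7a, named after its values were seen) and camera 0 lists, where the interferon list had a median of -0.13 and an adjusted p of 0.0909.

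The libraries did not separate by operation over all tested genes. The mean distance between libraries of different groups exceeded that within groups by 0.548 on a mean of 67.0, with an exact permutation p of 0.254 over all splits of the 10 libraries into 5 and 5. Without SG 2 the difference was -0.646, without SG 4 -0.61 and without SG 5 -0.552, and it was above 1.5 times its value without SHAM 1 (1.35), SHAM 2 (1.58), SHAM 3 (0.84), SHAM 4 (0.973) and SHAM 5 (1.62), with no p under 0.05. Without SG 1 it was 0.276, and on TPM it was -0.173. Clock genes and cholesterol synthesis genes varied between libraries within both groups. Dbp, an output gene of the circadian clock, ranged from 3.23 to 81.1 FPKM in SG and from 2.34 to 83.6 in SHAM. Arntl, a core clock activator, ranged from 0.21 to 7.91 FPKM in SG and from 0.44 to 7.22 in SHAM. Hmgcs1, of the first steps of cholesterol synthesis, ranged from 48.8 to 411 FPKM in SG and from 19.3 to 203 in SHAM. A clock score made from 7 genes minus 4 genes, chosen after the values were seen, was -0.44 ± 2.51 in SG and 0.44 ± 2.70 in SHAM (SD, n = 5, exact permutation p = 0.683, adjusted p = 0.825 over 5 scores).

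**Figure D3:**
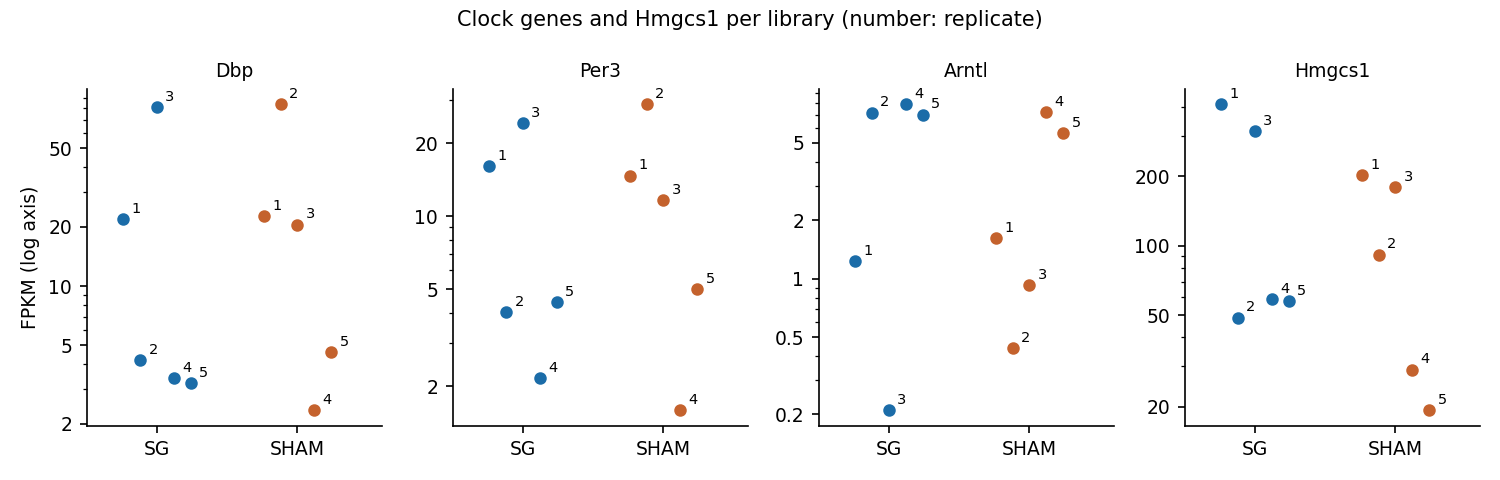
FPKM of the clock genes Dbp, Per3 and Arntl and of the cholesterol synthesis gene Hmgcs1 in each library (vertical log axes), with replicates numbered. Each group holds both low and high libraries: Dbp reached 81.1 FPKM in SG 3 and 83.6 in SHAM 2.

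Long non-coding RNAs were the stated subject of the series. The RNase P RNA Rpph1, which processes transfer RNA precursors, was the most abundant in the list, at 3857 ± 579 FPKM in SG and 2769 ± 355 in SHAM (SD, n = 5), with a log2 fold change of 0.40 ± 0.19 (SE). The telomerase RNA Terc stood at -0.13 ± 0.36, which was 0.01 without SG 4 and 0.02 without SG 5, and the gene Tug1 had 4.30 FPKM in SG and 3.84 in SHAM. Among the known long non-coding RNA genes fixed before the data were examined, 3 were tested (Rpph1, Tug1 and Terc), with a median of 0.02, and 0 passed over all genes or adjusted over the list alone. Tested as a gene, Rpph1 had a log2 fold change of 0.39 and an unadjusted p of 0.0362 in edgeR. An isoform of LOC102548818 had 0.74 ± 0.52 (0.42 without SG 5) and Kantr 0.40 ± 0.40 (0.08 without SG 1). Isoforms of LOC103692984, 2 in number, had -0.76 ± 0.89 (-0.44 without SHAM 4) and -0.60 ± 1.06, which ranged from -1.06 without SG 2 to -0.28 without SG 4. Of the 34 known long non-coding RNA genes fixed in the list, 4 had gene values here. H19, Meg3, Malat1 and Neat1 were not among them and were not analysed. Before the filter 41 transcripts were classed as long non-coding, so the counts of 0 here cover few long non-coding RNAs. Of 20 annotated long non-coding transcripts tested, 0 passed in edgeR and 0 had an unadjusted p under 0.05; limma on log2(FPKM + 0.1) called 0, with 1 at an unadjusted p under 0.05. Single transcripts were measured less firmly than genes: in simulated data edgeR recovered 0% of 2-fold, 6% of 4-fold and 54% of 16-fold changes among 39559 transcripts. The simulated p-values were adjusted over all 39559 transcripts together, and those of the long non-coding transcripts over their 20 tests only. These shares are therefore not the recovery of the long non-coding test.

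Among transcripts assembled without a reference identifier, 2 passed in edgeR. MSTRG.5179.1, a spliced transcript of 2 exons and 280 nt on the minus strand of chromosome 11 (74065445 to 74065838, Rnor_6.0), lies antisense to Cpn2, which encodes a subunit of carboxypeptidase N. It had 83 to 169 counts in the 5 SG libraries and 0 in every SHAM library, at least 193.7-fold higher by total counts against a floor of 3 counts over the group (adjusted p = 0.0391). Cpn2 itself had 98.9 FPKM in SG and 89.5 in SHAM, a log2 fold change of 0.05 ± 0.12 (SE). Whether counting used strand is not given in the sources used here, so reads of this transcript and of Cpn2 may be mixed. MSTRG.2939.1, an intergenic transcript of 4 exons on chromosome 1 (274167591 to 274169464), had 1 count over the SG libraries and 31 to 142 in each SHAM library, a SHAM to SG ratio of 508 by total counts with a 95% counting interval from 90.8 to 20125 (edgeR adjusted p = 0.0391). All isoforms of its locus together had 299 to 604 counts in SG and 281 to 389 in SHAM. Summed over loci, a test added after the data were seen, 1 of 8415 intergenic, intronic and antisense loci passed in edgeR, MSTRG.5179 (adjusted p = 0.00981), and limma also called 1. MSTRG.5179 holds 1 isoform, MSTRG.5179.1, so its call is no separate support.

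The test behind these calls covered 20989 unannotated transcripts. At an unadjusted p under 0.05 there were 896, where 1049 would be expected with no difference, and limma on log2(FPKM + 0.1) called 4, which were both of the above, MSTRG.7467.3 and MSTRG.24238.3. The count was 0 without SG 1, SG 4, SG 5, SHAM 2, SHAM 3 or SHAM 4, and 4 without SHAM 1 or SHAM 5. Without SG 2 it was 3 (MSTRG.13315.1, MSTRG.19396.1 and MSTRG.20278.3) and without SG 3 it was 2 (MSTRG.7457.2 and MSTRG.18676.22), none of them called by edgeR with all libraries. Limma called MSTRG.13315.1 with all libraries on log2(FPKM + 0.01) (adjusted p = 0.0125) and on TPM (0.0488). Besides the transcripts above, MSTRG.3288.2 and MSTRG.23495.1 passed without SHAM 1, and MSTRG.2981.4, MSTRG.10736.1 and MSTRG.24341.2 without SHAM 5; these were named after their values were seen. Left out 1 library at a time, MSTRG.5179.1 passed in 2 of 10 fits (adjusted p from 0.025 to 0.173) and MSTRG.2939.1 in 1 of 10 (0.025 to 0.227). Their log2 fold changes in these fits were 9.85 to 10.06 and -9.58 to -7.99. Over all alternatives they passed in 9 of 20 and 5 of 19. Neither passed in edgeR with no filter (adjusted p = 0.0735 and 0.0872) or with the replicate number as a block. MSTRG.7467.3 had 2618 to 24482 counts in the SG libraries and 0 in every SHAM library. The next lowest p-values belonged to MSTRG.24238.3 at Cask and MSTRG.7467.3 on the higher side, and to MSTRG.7014.1 and MSTRG.10736.2, within Nedd4l, on the lower side. None of these 4 passed in edgeR (adjusted p = 0.231 for the first pair and 0.443 for the second).

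**Figure D4:**
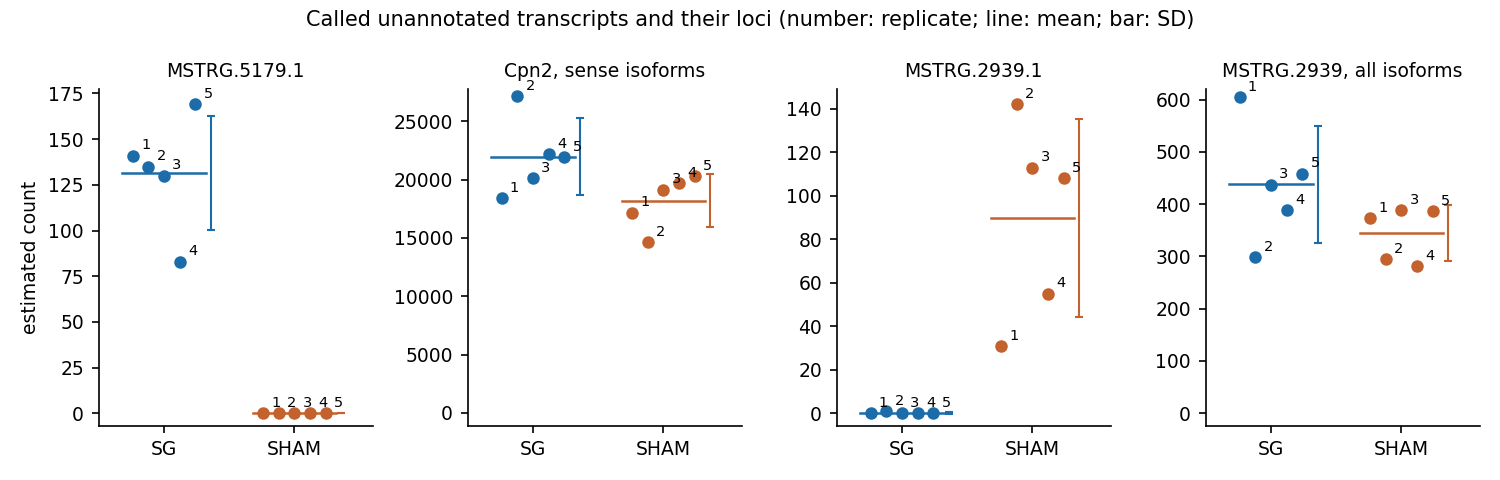
Estimated counts per library (vertical axes) of MSTRG.5179.1, the sense isoforms of Cpn2, MSTRG.2939.1 and all isoforms of the MSTRG.2939 locus, with replicates numbered, lines at group means and bars for the SD of 5 libraries. MSTRG.5179.1 holds 83 to 169 counts in SG and 0 in SHAM, while Cpn2 counts overlap.

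Annotated transcripts gave no call. Isoforms of the oligoribonuclease gene Rexo2 went opposite ways: ENSRNOT00000087265 had 7.10 ± 1.88 FPKM in SG and 1.28 ± 0.63 in SHAM (SD, n = 5), and ENSRNOT00000047633 had 3.42 ± 1.06 and 8.55 ± 1.48. An isoform of Nfat5, a transcription factor of the osmotic stress response, stood at a log2 fold change of 3.93 ± 0.59 (SE), and isoforms of the decapping enzyme gene Dcp2 and of Mbnl3 at -2.86 ± 0.61 and -3.57 ± 0.78. None of these passed (edgeR, adjusted p from 0.501 to 1). Of 18550 annotated transcripts 0 passed in edgeR, with 733 at an unadjusted p under 0.05 where 928 would be expected with no difference, and limma on log2(FPKM + 0.1) called 0, with 910. The count was 1 without SG 5 (an isoform of AABR07072266) and 1 without SHAM 1 (an isoform of Nbr1), both named after their values were seen.

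Neighbouring genes were asked whether they moved with long non-coding RNAs. Over 20 pairs of a long non-coding transcript and the nearest tested protein-coding gene that did not overlap it (14 genes), the median absolute difference of log2 fold changes was 0.31 (permutation p = 0.74 over 1000 random pairings). Spearman's rho across pairs was 0.04 (permutation p = 0.423), and pairs are not independent replicates. The rho was 0.44 without SG 2 (p = 0.029 by the same permutation test). It turned negative without SG 1 (-0.15), SG 3 (-0.13), SG 4 (-0.21), SHAM 1 (-0.01) or SHAM 4 (-0.17), was 0.01 without SG 5, and was 0.24 to 0.27 without SHAM 2, SHAM 3 or SHAM 5. Over assembled intergenic loci, pairs added after the data were seen, the rho was 0.20 for 692 pairs within 10 kb (permutation p = 0.001, the smallest that 1000 random pairings can give), 0.02 for all 5704 pairs (p = 0.045 by permutation) and -0.03 beyond 100 kb (p = 0.952 by permutation). The median absolute difference was 0.38 over all of these pairs and 0.27 within 10 kb (permutation p = 0.001 each), and 0.42 beyond 100 kb (permutation p = 0.516). Random pairings reuse the same fold changes, so these p-values do not measure the spread between samples and say nothing about the operation. Whether loci within 10 kb are unannotated parts of the neighbouring gene was not tested.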

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

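All tests of explanations in this part were written down after the results they measure had been seen.

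In 29 of 244 groups of 5 libraries tested, 1 library lay far from the other 4. About 1 in 20 groups, or 12, would pass this cutoff by chance if values were normal and independent. FPKM and counts were tested untransformed, and many items shared libraries, so 29 against 12 does not show an excess. Of the 29, 12 were in SG 2 and 4 in SHAM 5. In SG 2 these were FPKM of Scd (155), Lyz2 (81.64), C1qc (73.32), Jchain (63.38), Cd68 (18.04), Col1a1 (5.25), Acta2 (4.67), Cd22 (3.73) and Asns (1.56), the scores of the extracellular matrix list (0.98) and the xenobiotic list (-0.82), and the count of MSTRG.2939.1 (1), where any single count beside libraries at 0 would stand apart. In SHAM 5 these were FPKM of Irf7 (112.72), Usp18 (49.23) and Ube2l6 (14.59) and the interferon score (2.4). Among single genes elsewhere were Cyp7a1 (107.67) and Cpt1a (161.94) in SG 1, Ppargc1a (3.71) in SG 3, Mup4 (8036.63) in SG 4 and Irf9 (5.43) in SG 5. In SHAM they were Igf1 (42.67) in SHAM 1, Sds (92.67) and Cyp4a8 (4.16) in SHAM 2 and Fgf21 (37.79) in SHAM 4, all in FPKM. The lipoprotein score was -0.33 in SG 3 and the hepatocyte score 0.24 in SHAM 4. Reads at ribosomal loci made up 8.794% of counts in SG 3, and intergenic transcripts 4.727% in SHAM 3.

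Small RNA families outside the gene comparisons were looked at last. RF00100, the 7SK RNA family, had 5724 RPM on average in SG, counted outside ribosomal loci, 1.27 times its SHAM mean, and every SG library lay above the SHAM libraries (4230 to 4853). Its exact permutation p was 0.00794, the smallest that 5 against 5 libraries can give, and 0.321 adjusted over 81 families. RF00001, the 5S ribosomal RNA family, was lower in every SG library, and 0.64 families without overlap would be expected by chance.

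The first pattern was the lower interferon list in SG. Chance could not be excluded, since 98 of 100 splits of the libraries called this 1 list in either direction. Its median log2 fold change was -0.06 without SHAM 5, and the list passed without each of the other 9 libraries. The level of this 1 sample may thus account for the list call. Irf9 stood at -0.75 and Ifi27 at -0.49 without it. Both were named for their low p-values in these same data, so they do not show that a difference remains. More macrophages in SHAM 5 as the source could not be excluded. There 15 of 16 macrophage markers were higher than the mean of the 9 others, by a median of 0.94 log2. Interferon genes rose more, by a median of 1.99. The upper quartile of the markers was 1.26 and the lower quartile of the interferon genes 1.33. A smaller rise of markers cannot rule out macrophages as a full or partial source. An infection or another state of that rat remains open and was not tested.

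The second pattern was the pair of called unannotated transcripts. As many calls came from 43 of 100 splits, with 2 in the real split and up to 18 in another, so chance could not be excluded. For MSTRG.2939.1, reads moved between isoforms of the locus may be the source, since the summed locus had a log2 fold change of 0.20. For MSTRG.5179.1, a fixed share of Cpn2 reads would predict 545 counts in SHAM, and 0 were seen. The transcript was singled out for its 0 counts there while Cpn2 was near equal, so this prediction had to miss and decides nothing. A share of Cpn2 reads that differs between libraries was not tested. Transcripts with at least 10 counts in all libraries of 1 group and 0 in the other numbered 4 in the real split. All 4 were on in SG, MSTRG.5179.1 and MSTRG.7467.3 among them. Of all splits into 5 and 5, 44 had as many (highest other 10). An effect of the operation on MSTRG.5179.1 stays open.

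The third pattern was the spread of clock and cholesterol genes. Another split, SG 1, SG 3, SHAM 1, SHAM 2 and SHAM 3 against the rest, called 213 genes where the real one called 0, which points to a structure of the samples. The operation as its source is argued against, since 2 of 5 SG and 3 of 5 SHAM libraries had a clock score above 0. On log2(FPKM + 0.5), Dbp and Arntl lay on opposite sides of their means in 10 of 10 libraries, and on FPKM in 7 of 10, which the hour of collection could produce, but the labels give no hours, so this cannot be told apart from other causes of clock differences.

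For the 509 genes at an unadjusted p under 0.05, 42 of 100 splits gave as many, with up to 1945 in another split. For the 1 list called, 100 of 100 splits gave as many, with a median of 8 and up to 15 in others, so several list calls arose in most other groupings of these libraries. Chance was excluded for neither count. The counts of 0 genes, 0 long non-coding and 0 annotated transcripts are reached by any split (100 of 100), so splits say nothing about chance there; other splits called up to 213, 1 and 4.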

How the results depend on the processing

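Among planned settings, limma, TPM, median-of-ratios, quantile and filter settings left the gene count at 0, and the cause of each change given here was not tested unless stated. Genes numbered 101 by an unadjusted p under 0.05 with a 2-fold change, 16 in DESeq2, 1 without SG 2 and SHAM 5 together, and 0 to 1 with 1 library left out. Unannotated transcripts numbered 4 in limma with 0.1 or 1 added, 7 with 0.01 added, 8 on TPM, 0 with no filter, where more transcripts were tested, 1 at a mean of at least 0.5 FPKM, 664 by the unadjusted threshold and 0 to 4 with 1 library left out. Annotated transcripts numbered 463 by that threshold and 0 to 1 with 1 library left out. Lists numbered 4 in limma at each pseudocount, adding oxidative phosphorylation (adjusted p = 0.032 with 0.5 added), urea cycle (0.032) and macrophage markers (0.0484), 5 without a filter (adding urea cycle, stellate cell, red blood cell and B and plasma cell lists), 0 with an estimated correlation or fry's test for 1 direction (1 in either direction), 2 without partly overlapping isoforms, 3 with the clock score as a covariate (adding cholesterol synthesis and macrophage markers) or the ribosomal share (adding urea cycle and endothelial markers), 0 without SG 2 and SHAM 5 together, and 2 to 10 with 1 library left out. With an estimated correlation 0 lists were called in any fit with 1 library left out, and the p-values of the added lists were 0.393 (oxidative phosphorylation), 0.322 (urea cycle) and 0.407 (macrophages) in limma with 0.5 added, 0.265 (urea cycle) without partly overlapping isoforms, 0.167 (urea cycle) and 0.25 (endothelial) with the ribosomal share, 0.248 (urea cycle) and 0.274 (stellate cells) without a filter and 0.295 (macrophages) with the clock score. With 1 library also left out these calls held in 7 (not without SG 2, SHAM 2 or SHAM 3), 4 (not without SG 2, SG 4, SG 5, SHAM 3, SHAM 4 or SHAM 5) and 7 (not without SG 4, SG 5 or SHAM 5) of 10 fits. Named genes kept their sign under DESeq2 in all 68 cases. Signs turned for 1 named gene without partly overlapping isoforms, 4 on reference isoforms or without SG 2 and SHAM 5, 3 with the clock covariate and 2 with the ribosomal covariate. Among the 25 lists, signs turned for 1 on reference isoforms, 3 with the clock covariate, and 5 each with the ribosomal covariate or without SG 2 and SHAM 5.

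The replicate number as a block gave 0 genes (455 at an unadjusted p under 0.05), 0 unannotated transcripts and 4 lists, adding extracellular matrix, urea cycle and stellate cell lists, at p-values of 0.359, 0.411 and 0.135 with an estimated correlation. Libraries with like numbers correlated at 0.06, -0.22, -0.03, 0.01 and 0.14 in their deviations from the group means, and 1 of 5 SG libraries correlated best with its own number. No pairing by number was thus seen over all genes. A matching of rats that leaves no such correlation cannot be excluded.

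Group separation turned to -0.173 on TPM and -0.000286 by Spearman distance, and ranged from -0.646 to 1.62 with 1 library left out. It was 0.0623 with median-of-ratios size factors and 0.286 at a mean of at least 5 FPKM. The neighbour rho turned to -0.29 with 1 added to FPKM, ranged from -0.21 to 0.44 with 1 library left out, and over assembled intergenic loci was 0.02, with 0.20 within 10 kb and -0.03 beyond 100 kb.

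In limma camera's direction, which is relative to all genes (median 0.08 with 0.5 added), turned from up to down, while medians were positive, for glycolysis (median 0.07 at each pseudocount), cholesterol synthesis (0.20, and 0.21 with 0.1 added) and lipoproteins (0.14 with 0.1 or 0.5 added), and the log2 fold change turned positive for Pck1 (0.03), Insr (0.07) and Fgf21 (0.02 with 0.5 added and on TPM, 0.17 with 0.1 added). With 1 library left out, medians of lists whose camera direction turned ranged from -0.17 to 0.05 (gluconeogenesis), -0.14 to 0.04 (glycolysis), -0.15 to 0.30 (fatty acid synthesis), -0.23 to 0.33 (cholesterol), -0.17 to 0.03 (bile acids), -0.07 to 0.15 (lipoproteins), -0.05 to -0.02 (insulin), 0.02 to 0.26 (acute phase), -0.07 to 0.19 (inflammation), -0.10 to 0.25 (extracellular matrix), -0.21 to 0.05 (xenobiotic), -0.26 to 0.02 (clock), -0.05 to 0.15 (cell cycle) and -0.53 to 0.03 (macrophage). Medians turned without the camera direction for fatty acid oxidation (-0.06 to 0.19), oxidative phosphorylation (-0.01 to 0.07) and immediate early genes (-0.07 to 0.29). The endothelial median ranged from 0.0 to 0.24. Log2 fold changes ranged from -0.17 to 0.19 (Pck1), -0.08 to 0.45 (G6pc), -0.13 to 0.80 (Fasn), -2.29 to 3.03 (Scd), -0.71 to 0.13 (Nr0b2), -1.91 to 0.81 (Fgf21), -0.37 to 0.05 (Ppargc1a), -0.32 to 0.08 (Cpt1a), -0.07 to 0.03 (Insr), -0.11 to 1.53 (Col1a1), -0.01 to 1.16 (Idi1), -0.52 to 0.02 (Cd22) and -0.46 to 0.02 (Terc transcript).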

Other observations

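The gene groups and tests in this part were chosen after the data were seen. Of 75 ribosomal protein genes, 61 had a positive log2 fold change (median 0.18) and 23 an unadjusted p under 0.05 on the higher side. The median was 0.28 in limma on FPKM and 0.16 to 0.22 with 1 library left out. The count of 23 was 31 in limma on FPKM, 11 on TPM, 15 on reference isoforms and 15 without SG 2. Their camera p was 0.0661 with an estimated correlation, their fry p 0.0328, and their mean score 0.09 ± 0.12 in SG and -0.09 ± 0.11 in SHAM (SD, n = 5, exact permutation p = 0.0556, adjusted p = 0.139 over 5 scores). Of 295 pathways named in the deposited table, 2 passed camera with a preset correlation: Ribosome (146 genes, median 0.14) and Proteasome (44 genes, median -0.20), at an adjusted p of 1.24e-08 each. With an estimated correlation their p-values were 0.0419 and 0.114 (adjusted p = 0.996), and 0 pathways passed there or in fry.

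Immunoglobulin genes, products of B and plasma cells, were singled out because of their values, so a test of their difference on these libraries decides nothing. Ighg1 had 2.05 to 25.4 FPKM in SG and 0.68 to 3.03 in SHAM, Ighm 65.5 to 211 and 18.4 to 95.8, and Jchain 19.5 to 63.4 and 5.50 to 24.4. Their mean score was 0.92 ± 0.80 in SG and -0.92 ± 0.86 in SHAM (SD, n = 5). SG 2, which stands apart in other genes, had the highest score (2.03), and SG 3 (-0.07) lay below SHAM 3 (0.40). Each missed the threshold in edgeR (adjusted p = 0.993), and DESeq2 called Ighg1.

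Intergenic transcripts took 3.46 ± 0.177% of counts in SG and 4.05 ± 0.384% in SHAM (SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0873 over 11 measures). Without ribosomal loci the shares were 3.36 ± 0.196% and 3.56 ± 0.175% (exact permutation p = 0.143). Ribosomal loci took 5.30% in SG and 8.14% in SHAM on average, between 3.92% and 11.9% in single libraries (exact permutation p = 0.0714, adjusted p = 0.157).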
